A study of Mus musculus with 8 samples.

How the data were processed

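Total RNA from the medial prefrontal cortex (anterior cingulate subregion, both hemispheres) of 8 mice of the strain B6.SJL, aged 3 months, was sequenced. Samples were grouped by their titles into 4 context controls and 4 contextual fear conditioning samples, which the series design text calls biological replicates. RNA was extracted with a column kit and libraries were made by the sequencer maker's protocol, per the labels' protocols. Library type and strandedness are not given in the sources used here, so overlapping and antisense genes cannot be separated.

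The deposited file holds 22609 rows of gene symbols and 8 columns, and all 8 columns were used. It is named FPKM (a length-corrected unit). Its values are not length corrected. In each column, 100% of the values above 0 were whole multiples of a single step, within 0.01 of a read, so each column is a set of gene read counts divided by a factor of its own. The deposited values were therefore treated as a scaled count signal. The step ranged from 0.831 in context control replicate 1 to 1.61 in context control replicate 4. TopHat and HTSeq are named without versions, per the submitters' processing notes. The build named there is hg19, a human build, although the samples are mouse and the symbols are mouse symbols. No coordinates are printed for that reason. How the factor per sample was set, the gene annotation and any filter are not given in the sources used here. In the deposited symbols, 25 had been turned into calendar dates by a spreadsheet and could not be named.

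Dividing each column by its step recovered between 1992452 and 3565356 gene reads per sample, with 14276 to 15161 genes above 0. The depth did not separate the groups (exact permutation p = 0.857, two-sided). The median 95% confidence interval of a log2 change reached 0.62 to either side over all tested genes. It reached 0.41 for the 6532 genes with a mean value of at least 100. Replicate libraries were compared by a chi-square test on recovered reads. The chi-square per degree of freedom lay between 2.50 and 23.6 for the 12 pairs within groups, so no library was a copy of another in its group. Pairs across the groups were not compared in this way.

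Values were transformed to log2(value + 1), and genes with a mean value of at least 1 over the 8 samples were tested, 14704 in all. Fold changes are on this scale, which understates the change of genes with low values. Fear conditioning was compared with context control in limma 3.58.1 under R 4.3.3 (lmFit, and eBayes with a variance trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The test, the filter and the pseudocount were fixed before the data were examined, on the assumption of FPKM values. For a file of raw counts, the plan named edgeR (quasi-likelihood) as the main test instead. The file held scaled counts, and limma was kept as the main test for that reason. edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered reads as alternatives, a choice made after the values had been seen.

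Gene lists for pathways, cell types and RNA quality were written before the data were examined, and members were matched by current or unique older symbols. The 32 lists with at least 5 tested members were tested with limma's camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 32. camera with a correlation estimated per list and fry were run beside it. At the preset correlation camera takes its degrees of freedom from the number of genes, and with an estimated correlation from the samples. Its preset p-values therefore rest on genes rather than animals as units. The list score of a sample, the mean log2 value of the tested members, was compared by an exact two-sided permutation test over the 70 assignments of 8 samples, whose smallest possible p is 0.0286. Lists of blood cell and mitochondrially encoded transcripts had fewer than 5 tested members and were not tested. The sex-linked list served only as a sample check.

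Named genes followed a rule fixed before the data were examined. It took up to 10 genes per direction past the threshold, or where fewer passed, 5 per direction by smallest p, passing over predicted and unnamed loci. It always took 14 genes whatever their result, Fos, Fosb, Junb, Egr1, Egr2, Nr4a1, Npas4, Arc, Homer1, Bdnf, Dusp1, Per1, Sgk1 and Fkbp5. For each list described gene by gene it took the 2 members with the smallest p where none passed. Of the genes this rule takes from those lists, 1 is not reported here. Genes chosen after their values were seen are marked as such.

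GC content was taken from the longest GENCODE vM21 transcript of each symbol, which gave a value for 14530 (98.8%) of the tested genes, 13260 (90.2%) by current symbol. GC correction subtracted a lowess curve (span 0.3) of each library's deviation from the gene mean on GC content, fitted on genes with a mean log2 value above 5. It was chosen after seeing the data, as were fits on replicates 1 and 2 only, on replicates 3 and 4 only, and with that division as a term. The alternatives fixed beforehand were other pseudocounts and filters, median-of-ratios and quantile scaling, robust variance, no variance trend, array weights, the replicate number as a block, an adjusted p threshold of 0.1 and each sample left out in turn.

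The fits were tested on simulated counts with the real genes' means and library sizes, with 50 genes changed per fold size. The changed genes were drawn only from genes with means well above the filter, so the shares recovered do not cover genes near the floor. In the simulated comparison of fear conditioning with context control, limma over 14527 genes recovered 0% of the genes changed 1.5-fold, 38% of those changed 2-fold, 80% at 4-fold and 100% at 8-fold, with 8 false calls. edgeR over 14704 genes recovered 0%, 38%, 82% and 100%, with 11 false calls. A list shifted by 0.5 on the log2 scale was fitted at 0.46 and was the only list called. Counts were drawn independently for each gene, so the simulation cannot show how often camera calls unchanged lists whose members are correlated. It also held no shared difference between sets of replicate numbers, which the real libraries show below. Changed genes of all fold sizes were adjusted together, which eases the threshold for each. The shares may therefore overstate what the real comparison could detect. Figures were drawn with matplotlib 3.10.9.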

Results

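The transcriptome of the mouse medial prefrontal cortex was measured 1 h after a single training session, to ask how the neocortex changes early in the encoding of a memory. Mice in the conditioning group spent 3 min in a chamber, received 2 foot shocks of 0.8 mA for 2 s each with 30 s between them, and stayed 15 s longer. This pairs the place with an aversive event and is known as contextual fear conditioning. Context controls saw the same chamber without a shock. Each group held 4 biological replicates per the series design text. Recovered gene reads per sample were 3565356, 2327022, 3069259 and 1992452 in context control replicates 1 to 4, and 2306717, 2397648, 2413605 and 3338920 in fear conditioning replicates 1 to 4. Values below are gene read counts scaled by a factor per sample, given as mean ± SD with n = 4 per group. All 8 samples carried male transcripts, with the Y-linked Ddx3y between 294 and 527 and the X-inactivation transcript Xist at or below 1.33.

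No gene passed the threshold after fear conditioning, with 0 higher and 0 lower among 14704 genes by limma. The gene with the smallest p, Mical3, which encodes a flavoprotein monooxygenase acting on actin, was 25.1 ± 4.9 in context controls and 60.0 ± 4.1 after conditioning (SD, n = 4), a log2 change of 1.24. The next higher genes were Traip, a ubiquitin ligase (5.75 ± 2.25 and 18.8 ± 3.87), and 3 genes near the floor of detection, Spink10 (1.0 ± 1.5 and 8.61 ± 3.61), the adaptor gene Sla2 (0.50 ± 1.0 and 6.15 ± 2.52) and Fam71e1 (0.208 ± 0.415 and 4.56 ± 2.11). On the lower side stood Uevld (105 ± 10.03 in context controls, 32.0 ± 34.6 after conditioning), Coch, which encodes the extracellular matrix protein cochlin (232 ± 107 and 62.5 ± 58.2), the lipopolysaccharide-binding protein gene Lbp (19.5 ± 12.95 and 3.04 ± 4.38), the fructose transporter gene Slc2a5 (34.8 ± 10.3 and 14.4 ± 3.7) and the mTOR inhibitor gene Ddit4l (162 ± 71.8 and 67.4 ± 24.0). Over all tested genes, 282 (1.92%) separated the groups completely, where chance gives 2.86%. That chance value treats all samples as exchangeable and ignores the difference between sets of replicate numbers described below.

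The smallest adjusted p was 0.9998 in limma. At an unadjusted p under 0.05 there were 397 genes, 173 higher and 224 lower, where 735.2 would fall by chance. edgeR and DESeq2 on the recovered reads also called 0 genes, with 385 and 340 at an unadjusted p under 0.05. Leaving out fear conditioning replicate 4, where Uevld read 83.5 against 9.565 to 19.9 in the other conditioned samples, gave Uevld a log2 change of -2.79 with an adjusted p of 0.0065 in limma.

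The immediate early transcription factors, genes that neurons induce within minutes of activity, did not pass as a group between conditioned and control cortex. Of 27 tested members, 13 were higher and 14 lower and none passed, over all genes or adjusted over the list alone. Fos was 260 ± 52.6 in context controls and 334 ± 102 after conditioning (SD, n = 4). Fosb was 228 ± 30.5 and 301 ± 127, Junb 70.6 ± 24.1 and 111 ± 67.8, Egr1 1819 ± 115 and 1826 ± 449, Egr2 182 ± 73.0 and 214 ± 121, Nr4a1 416 ± 67.8 and 440 ± 256, and Npas4, an activity-dependent factor largely restricted to neurons, 105 ± 9.82 and 77.0 ± 36.4. The members with the smallest p were Nr4a3, at 92.4 ± 9.19 and 152 ± 43.8, and Btg2, at 118 ± 21.1 and 76.9 ± 10.4, and each separated the groups completely. The list mean changed by 0.03 on the log2 scale and its median by -0.0037 (camera adjusted p = 0.398, and adjusted p = 0.834 with an estimated correlation). With array weights the mean was 0.17 and the list passed camera (adjusted p = 0.04, and adjusted p = 0.558 with an estimated correlation).

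The activity-induced effectors, whose products act mainly at synapses and in signalling, also had no member past the threshold, over all genes or adjusted over the list alone (32 tested, 21 higher and 11 lower, camera adjusted p = 0.492, and 0.834 with an estimated correlation as adjusted p). Arc, whose product regulates AMPA receptor endocytosis, was 696 ± 138 in context controls and 672 ± 381 after conditioning (SD, n = 4). The scaffold gene Homer1 was 1035 ± 122 and 1076 ± 211, and the neurotrophin gene Bdnf 343 ± 44.2 and 381 ± 75.9. Counts are per gene, so the transcript forms of a gene such as Homer1 were not told apart. Dusp1 was 215 ± 49.6 and 171 ± 26.6, and Trib1 255 ± 64.99 and 181 ± 43.0. Genes that respond to glucocorticoid hormones after stress also had no member past the threshold, over all genes or adjusted over the list alone, with 8 of 21 tested members higher and 13 lower (camera adjusted p = 0.69, and 0.834 with an estimated correlation as adjusted p). Among these, Per1 was 282 ± 75.3 and 422 ± 239.5, Sgk1 279 ± 128 and 332 ± 96.5, Fkbp5 105 ± 9.37 and 113 ± 10.4, Gjb6 315 ± 52.7 and 232 ± 34.1, and Pdk4 126 ± 56.8 and 91.9 ± 32.6.

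**Figure D1:**
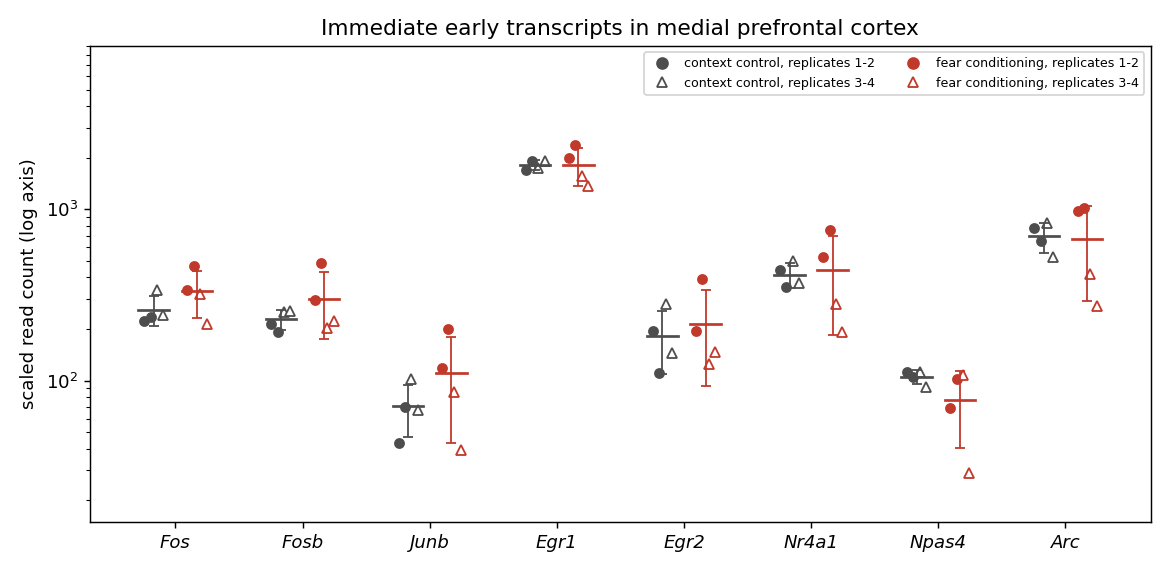
Scaled read counts of 8 activity-regulated genes in each of the 8 samples, on a log axis, with horizontal lines at the group means and bars of 1 SD (n = 4). For Arc, fear conditioning replicates 1 and 2 lie at 982 and 1013 and replicates 3 and 4 at 419 and 273, on either side of the context controls at 525 to 837.

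The change of these lists differed between sets of replicate numbers. In replicates 1 and 2, the conditioned samples were above the controls of the same numbers by a mean log2 change of 0.48 for the transcription factors and 0.34 for the effectors. In replicates 3 and 4 they were below by -0.41 and -0.28. Arc changed by 0.49 and -0.97, Junb by 1.47 and -0.50, Nr4a1 by 0.68 and -0.89, Fosb by 0.89 and -0.25, and Fos by 0.79 and -0.13 in the same order. Some members kept their direction, with Nr4a3 at 0.83 and 0.52, Npas4 at -0.36 and -0.85 and Btg2 at -0.32 and -0.88, and Homer1 stood at -0.0083 and 0.098. For the 59 members of both lists the difference between these changes was 0.75, and exact permutation of group labels within replicates 1 and 2 and within replicates 3 and 4 (36 relabellings) gave p = 0.0556, the smallest that this design allows, so it could not pass 0.05. The difference of the changes passed for 0 genes in limma (742 at an unadjusted p under 0.05). It passed in camera for 10 of the 32 lists, both of these among them (adjusted p = 1.17e-09 and 3.76e-06), and for 0 lists with an estimated correlation (adjusted p = 0.362 for each of these). This division of the samples was chosen after seeing the data.

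Lists of glial, vascular, meningeal, choroid plexus and inflammatory transcripts, 8 in all, were lower after conditioning by camera at its preset correlation. None of these calls held with an estimated correlation, where the adjusted p lay between 0.321 and 0.464. All 17 tested members of the endothelial and mural list lay lower, with a mean log2 change of -0.45, among them the vascular receptor gene Tek (137 ± 34.9 and 84.9 ± 30.8) and Pecam1 (168 ± 11.6 and 113 ± 41.9). All 15 astrocyte members lay lower, with a mean of -0.29, including the connexin genes Gja1 (1239 ± 151 and 991 ± 70.1) and Gjb6. All 10 oligodendrocyte precursor members lay lower, with a mean of -0.43, including the sialidase gene Neu4 (40.8 ± 4.97 and 21.1 ± 4.39, every conditioned sample below every control) and the lineage factor gene Olig2 (83.1 ± 21.1 and 52.5 ± 18.6). camera gave these lists adjusted p = 6.46e-05, 0.000954 and 0.000954, and each had an adjusted p = 0.321 with an estimated correlation.

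Mature oligodendrocyte transcripts lay lower in 16 of 16 members (mean -0.58), with Trf, encoding transferrin, at 632 ± 465 and 343 ± 83.0, and Ppp1r14a at 7.50 ± 5.27 and 3.04 ± 2.29. Trf read 1320 in context control replicate 3 and 301 to 478 in the other controls, and its log2 change was -0.24 without that sample. The meningeal fibroblast list was lower in 14 of 14 members (mean -0.56), with Slc13a4 at 45.2 ± 26.8 and 22.4 ± 10.2 and decorin, Dcn, at 113 ± 64.05 and 66.2 ± 36.7. The interferon and inflammation list was lower in 11 of 12 (mean -0.44), with Oasl2 at 21.3 ± 16.4 and 7.16 ± 1.78 and Irf7 at 3.77 ± 2.03 and 1.66 ± 3.32. Microglial transcripts were lower in 12 of 14 (mean -0.21), with Aif1 at 37.6 ± 8.50 and 23.4 ± 8.85, whereas Fcrls lay higher at 96.2 ± 35.4 and 145 ± 44.7. Choroid plexus transcripts were lower in 6 of 7 (mean -0.58), all near the floor in the examples Kcnj13 (3.55 ± 1.65 and 0.663 ± 1.33) and Sostdc1 (6.51 ± 3.47 and 6.20 ± 10.7). Their camera adjusted p were 0.000984, 0.000954, 0.0146, 0.0147 and 0.023 in the order named, and with an estimated correlation the adjusted p were 0.464, 0.46, 0.336, 0.336 and 0.336.

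No member of the 8 lists passed over all genes or adjusted over the list alone. Exact permutation of the list scores gave adjusted p between 0.594 and 0.61. That adjusted test could hardly pass with 4 samples per group, so its failure does not count against the lists. Context control replicate 3 had the highest score of all samples in each of these lists except the microglial one. Without it, 3 of these 8 lists stayed past the camera threshold. The mean was then -0.08 for oligodendrocyte, -0.25 for meningeal, -0.24 for interferon and inflammation and -0.26 for oligodendrocyte precursor transcripts. Without fear conditioning replicate 3 it was -0.18 for meningeal, -0.29 for endothelial and mural and -0.28 for interferon and inflammation transcripts. Oligodendrocyte transcripts changed by -0.39 without fear conditioning replicate 2 and by -0.96 without context control replicate 4, choroid plexus transcripts by -0.36 without fear conditioning replicate 1 and microglial transcripts by -0.10 without fear conditioning replicate 4. The interferon and inflammation list lost its call with no filter (mean -0.28, camera adjusted p = 0.0825), quantile normalization (0.0745) and array weights (0.0855), the choroid plexus list with quantile normalization (0.124) and GC correction (0.0545), and the microglial list with array weights (0.114). The choroid plexus mean was -0.43 with quantile normalization, -0.61 with GC correction and -0.96 at a pseudocount of 0.1. With GC correction and the replicate number as a block the choroid plexus list passed again (camera adjusted p = 0.0206). With each of the 8 samples left out in turn, the endothelial and mural, astrocyte and oligodendrocyte precursor lists stayed past the camera threshold each time. In replicates 1 and 2 only, none of these 3 lists passed camera (adjusted p = 0.112, 0.423 and 0.0827). Their mean changes were -0.09, -0.07 and -0.29 within replicates 1 and 2, and -0.81, -0.52 and -0.57 within replicates 3 and 4. The mean changes of the 8 lists lay between -0.66 and 0.35 within replicates 1 and 2 and between -1.48 and -0.44 within replicates 3 and 4.

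The 5 lists that camera called higher were deep-layer neuron, potassium channel, presynaptic, ionotropic glutamate receptor and chromatin methylation genes, and none of these calls held with an estimated correlation (adjusted p between 0.321 and 0.336). The estimates were 0.38, 0.0002, 0.093, -0.0011 and 0.038 in that order. For the potassium channel and ionotropic receptor lists they lay below the preset 0.01, so correlation among members does not account for the loss of these calls. Their unadjusted camera p still rose, from 0.0043 to 0.0207 and from 0.0135 to 0.0358, since camera then takes its degrees of freedom from the samples. Other neuronal lists were not called in either direction, among them upper-layer neuron, interneuron, GABA receptor and postsynaptic density transcripts. The deep-layer excitatory neuron list was higher in 11 of 13 members, with a mean log2 change of 0.42 that was -0.12 in replicates 1 and 2 and 0.95 in replicates 3 and 4. It was 0.24 without context control replicate 4 (camera adjusted p = 0.114) and 0.27 without fear conditioning replicate 3 (0.077). Its examples were the transcription factor gene Foxp2 (46.6 ± 12.8 and 98.5 ± 55.8) and Nxph4 (2.84 ± 2.73 and 8.37 ± 4.73). Voltage-gated potassium channel genes were higher in 17 of 21 (mean 0.17), led by Kcnq3, a subunit of the M current (99.1 ± 15.0 and 144 ± 11.5, every conditioned sample above every control), and Kcng1 (37.2 ± 27.7 and 59.3 ± 17.5). Presynaptic vesicle genes were higher in 23 of 28 (mean 0.12), including Syn3 (205 ± 43.2 and 267 ± 16.6) and Nrxn3 (1078 ± 61.1 and 1267 ± 144). Ionotropic glutamate receptor genes were higher in 15 of 20 (mean 0.14), including the kainate receptor genes Grik4 (53.8 ± 12.6 and 82.5 ± 23.3) and Grik3 (367 ± 183 and 512 ± 136). Enzymes and readers of histone and DNA methylation were higher in 21 of 26 (mean 0.14), including the demethylase gene Kdm5c (184 ± 17.9 and 226 ± 17.8) and Mll1, the older symbol of Kmt2a (431 ± 218 and 543 ± 75.9).

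The camera adjusted p of these lists were 0.00122, 0.0147, 0.0145, 0.0332 and 0.0223 in that order, and no member passed over all genes or adjusted over the list alone. The potassium channel score was the only list score at an unadjusted exact permutation p under 0.05 (7.77 ± 0.085 and 7.95 ± 0.052, p = 0.0286, the smallest that 70 assignments can give, and adjusted p = 0.594). With array weights the potassium channel (camera adjusted p = 0.0855) and chromatin methylation (0.114) lists lost their call. The higher lists went from 5 to 1 under quantile normalization, to 2 without context control replicate 3, fear conditioning replicate 1 or fear conditioning replicate 3, and to 3 without fear conditioning replicate 2. Each of the 5 lost its call when at least 1 of the 8 samples was left out, the potassium channel list only without fear conditioning replicate 4 (mean 0.16, adjusted p = 0.179). The ionotropic glutamate receptor mean was 0.22, 0.07, 0.09 and 0.23 without context control replicates 2 and 3 and fear conditioning replicates 2 and 4. The chromatin methylation mean was 0.07 and 0.08 without context control replicates 3 and 4, and the presynaptic mean 0.18 without fear conditioning replicate 4. Apart from the deep-layer list, these lists were higher both within replicates 1 and 2 (means of 0.07 to 0.15) and within replicates 3 and 4 (0.12 to 0.24). The metabotropic glutamate receptor genes did not pass (6 of 7 higher, mean 0.24, camera adjusted p = 0.0683), with Grm8 at 165 ± 39.3 and 223 ± 60.8. They passed camera with replicates 1 and 2 against 3 and 4 as a term (mean 0.24, adjusted p = 0.0305) and with GC correction (mean 0.21, adjusted p = 0.0223), where the adjusted p with an estimated correlation was 0.405 and 0.365.

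**Figure D2:**
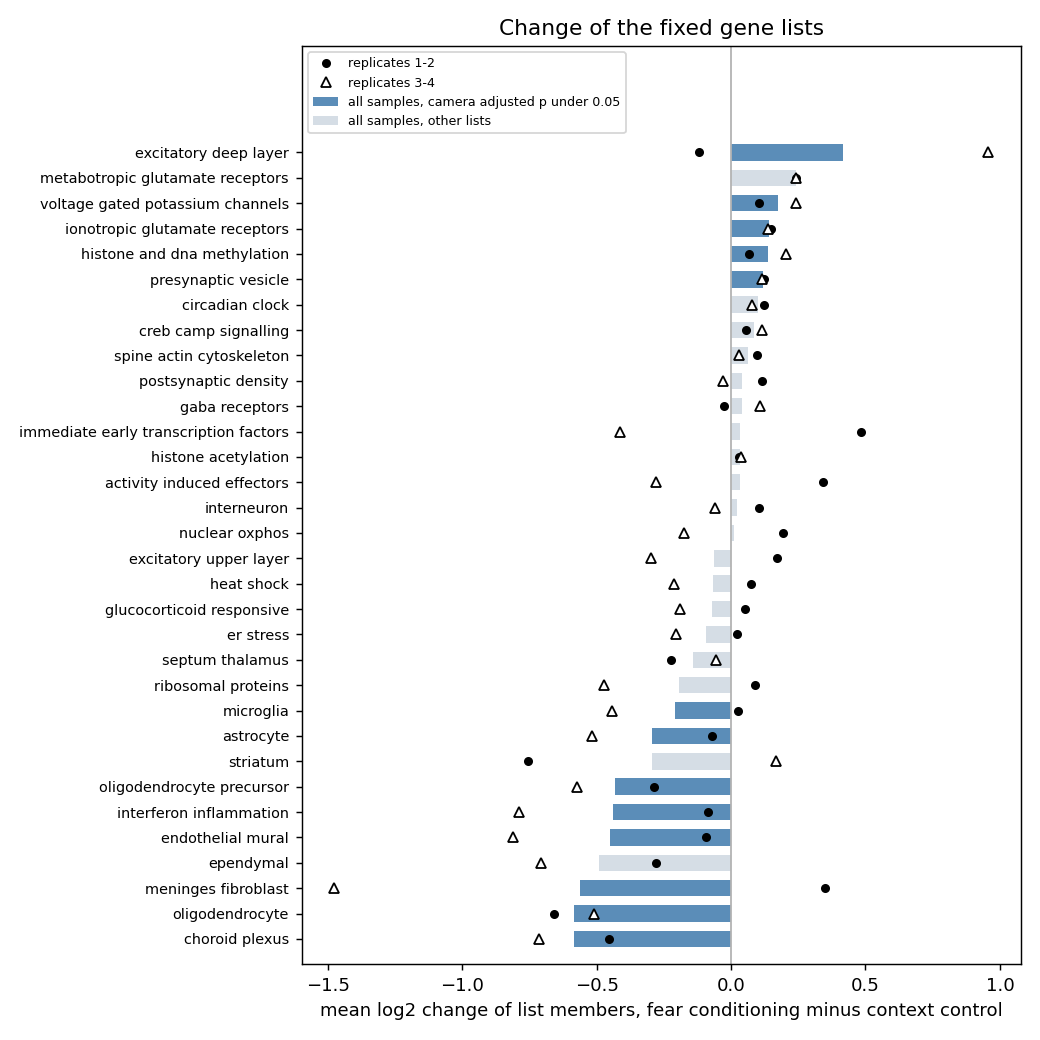
Mean log2 change of the tested members of each of the 32 gene lists, fear conditioning minus context control. Bars cover all 8 samples, with the 13 lists past the camera threshold in dark blue, and points show the change within replicates 1 and 2 (filled circles) and within replicates 3 and 4 (open triangles), such as 0.35 and -1.48 for the meningeal list.

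The other lists did not pass camera's threshold with all 8 samples and the settings fixed as main. Mean log2 changes were -0.49 for ependymal, -0.29 for striatal, -0.19 for ribosomal protein, -0.14 for septal and thalamic, -0.09 for endoplasmic reticulum stress, -0.07 for heat shock, -0.07 for glucocorticoid-responsive and -0.06 for upper-layer neuron transcripts. They were 0.10 for clock, 0.09 for CREB and cAMP signalling, 0.06 for spine actin, 0.04 for postsynaptic density, 0.04 for GABA receptor, 0.03 for histone acetylation, 0.02 for interneuron and 0.01 for nuclear-encoded respiratory chain transcripts, of which the postsynaptic density, GABA receptor and respiratory chain means turned negative under quantile normalization, the last also under median-of-ratios scaling. Their camera adjusted p lay between 0.0734 and 0.767. Single samples moved several of these means, to -0.24 for ependymal without context control replicate 3, -0.07 for striatal without context control replicate 2, -0.04 for endoplasmic reticulum stress without fear conditioning replicate 4, 0.04 for clock without fear conditioning replicate 2 and 0.03 for spine actin transcripts without context control replicate 1. Without context control replicate 4 the spine actin mean was 0.10. The ependymal, striatal, ribosomal protein, endoplasmic reticulum stress, CREB and cAMP signalling, spine actin and respiratory chain lists passed camera under at least 1 alternative, none of them with an estimated correlation. The mean and the median differed in sign for the immediate early, interneuron and heat shock lists.

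The libraries fell into sets of replicates that cut across the treatment. The first principal component, with 34.9% of the variance, set replicates 1 and 2 of both groups apart from replicates 3 and 4. By limma with the treatment as a term, 3546 genes differed between these sets, 2133 higher and 1413 lower in replicates 1 and 2. The deviation of genes from their mean followed GC content, with Spearman's rho across 9714 genes of 0.42, 0.60, -0.57 and -0.25 in context control replicates 1 to 4 and 0.63, 0.69, -0.36 and -0.77 in fear conditioning replicates 1 to 4. Genes are not independent replicates, so rho describes each library. The group means of rho were 0.047 and 0.048 (exact permutation p = 1). With this division as a term, 0 genes differed by treatment in limma (870 at an unadjusted p under 0.05, where 735.2 would fall by chance).

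**Figure D3:**
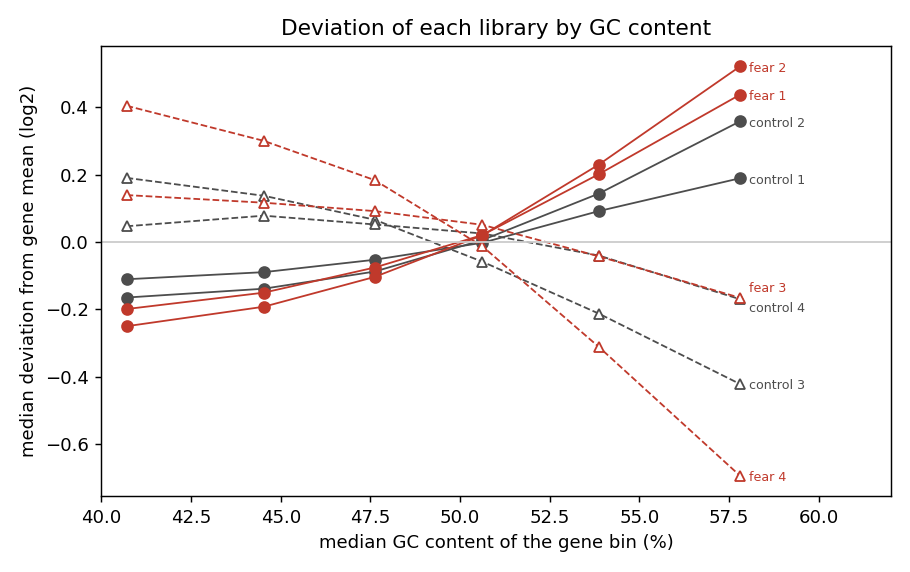
Median log2 deviation from the gene mean in each library, for 6 bins of 1619 genes ordered by GC content, against the median GC percentage of the bin. In the bin of highest GC content, replicates 1 and 2 of both groups lie between 0.19 and 0.52 and replicates 3 and 4 between -0.69 and -0.17.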

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

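The tests of GC content on the difference between replicate numbers and of other splits for genes were chosen after the result was seen. Samples far from the rest of their group were looked for in 176 groups of 4 samples, the 56 named genes and 32 list scores in each treatment. For 12 of them (6.82%) the gap of the extreme sample to its neighbour took more than Dixon's 95% critical share of the range. Chance flags about 1 in 20 groups of normally distributed values, which scaled counts need not be.

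Context control replicate 3 was the extreme sample in 4 of the 12. These were Fos at 338 (0.835 of the group's range), Sgk1 at 471 (0.897), Pdk4 at 211 (0.896) and Sla2 at 2.02 (1). Other context controls were Foxp2 in replicate 2 at 65.8 (0.914) and Fam71e1 in replicate 1 at 0.831 (1). In fear conditioning they were Mical3 in replicate 1 at 53.9 (0.897), Trf in replicate 2 at 219 (0.920), Kcnj13 in replicate 2 at 2.65 (1), Irf7 in replicate 2 at 6.63 (1), Sostdc1 in replicate 4 at 22.1 (0.876) and Uevld in replicate 4 at 83.5 (0.860). For Sla2, Fam71e1, Kcnj13 and Irf7 all other samples of the group read 0, so the share is 1 by construction and these flags carry little weight.

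The split of the samples by replicate number, 1 and 2 against 3 and 4, was the largest structure in the data. GC content bias between libraries would predict that correcting each library for its GC trend removes most of the difference. After the correction 631 genes differed, against 3546 before (82.2% fewer), so GC bias may account for most of these calls. The correction removes any difference that follows GC content, whatever its source, so it cannot tell a library bias from a biological difference. Of the 631, 394 also differed before the correction and 237 did not, and what set these genes apart stays open. The labels give no batch, so no biological explanation was tested.

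Glial, vascular, meningeal and choroid lists were lower after conditioning. Context control replicate 3 alone may carry part of this, since without it 3 of the 8 lists stayed lower and past the camera threshold, and the oligodendrocyte mean went from -0.58 to -0.08. The 3 that stayed, endothelial and mural, astrocyte and oligodendrocyte precursor, changed by -0.35, -0.22 and -0.26 without it, against -0.45, -0.29 and -0.43 with it (camera adjusted p = 0.0065, 0.0194 and 0.0403), so their camera calls did not need that sample, though with an estimated correlation they failed with and without it (adjusted p = 0.321 and 0.455 for each). In replicates 1 and 2 only, their camera calls were lost (adjusted p = 0.112, 0.423 and 0.0827). Context control replicate 3 was not the only such sample. Over all lists tested, 4 were lower and past camera without it, and also 4 without fear conditioning replicate 3, where the meningeal mean was -0.18. A lower share of all non-neuronal cells in the conditioned tissue cannot be told apart from separate changes of each type, because no pair of the 8 lists passed an exact permutation test of the difference (smallest p = 0.257) and the standard error of a difference between lists reached 0.73. The dissection and an effect of the training itself stay open and untested.

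Chance could not be excluded for the number of lists, since 3 of the 35 splits of the 8 samples into 4 and 4, the real one included, gave at least the observed 13 lists, and the highest of the others gave 14. For genes the splits cannot bear on chance, since the observed count was 0, which all 35 reach whatever the data. The highest of the other splits, 3601 genes, was the split of replicates 1 and 2 against 3 and 4, which points to a structure of the samples and gave 0 lists.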

How the results depend on the processing

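The GC correction, the fits on part of the replicates, the term for them, and the use of edgeR and DESeq2 on recovered reads were chosen after the result was seen. The counts of 0 genes higher and 0 lower held at an adjusted p of 0.1 and under every alternative run, except 2 genes higher in replicates 1 and 2 only (Obp1a and Gm5938) and 1 lower without fear conditioning replicate 4 (Uevld), a range of 0 to 1 with single samples left out. The 13 lists became 8 under quantile normalization, 5 in replicates 1 and 2 only, 0 with an estimated correlation and 0 with fry. They became 16 with replicates 1 and 2 against 3 and 4 as a term, which added the metabotropic glutamate receptor, endoplasmic reticulum stress and ribosomal protein lists (adjusted p = 0.0305, 0.0358 and 0.0311, and 0.405, 0.432 and 0.672 with an estimated correlation), 15 with GC correction and the replicate block, which added metabotropic and ribosomal (0.0206 and 0.0337), and 12 with array weights, where the potassium channel, chromatin methylation, interferon and microglial lists lost the call and immediate early, respiratory chain and spine actin gained it (0.04, 0.04 and 0.0443). Lists also gained a call as follows: metabotropic with GC correction (0.0223); effectors (0.000237), immediate early (7.2e-05), respiratory chain (0.0102) and striatum (0.000452) in replicates 1 and 2 only; effectors (0.0106), immediate early (0.000571) and ribosomal (0.000209) in replicates 3 and 4 only; ependymal with no filter (0.034) and without context control replicates 2 (0.0472) or 4 (0.0266); ribosomal without context control replicates 1 (0.0216) or 3 (0.0065) or fear conditioning replicates 1 (0.0071) or 2 (0.0063); spine actin (0.0378) and metabotropic (0.0483) without context control replicate 4; cAMP signalling without context control replicate 2 (0.0472); respiratory chain without fear conditioning replicate 4 (0.0318); endoplasmic reticulum stress with quantile normalization (0.0311). No list passed with an estimated correlation under any alternative run (smallest adjusted p = 0.268). At a pseudocount of 0.1 the mean was -0.92 for ependymal, -0.48 for striatal, -0.31 for ribosomal protein, -0.14 for glucocorticoid-responsive and -0.0081 for upper-layer neuron transcripts. With single samples left out the 13 lists ranged from 6 to 15, at 6 without context control replicate 3 or fear conditioning replicate 3. With those aside, over 1426 values of 88 named genes and lists, 1340 kept direction and side of the threshold, 24 lost and 17 gained the call, and 45 changed sign. Many of these values could hardly move, so the share kept is no measure of stability. Robust variance and no variance trend left every log2 change and camera value as in the main fit. The replicate block left every log2 change as it was, and the named genes started at an adjusted p of 0.9998 in limma. At this depth the simulated 1.5-fold changes were not detectable. The cause of the changes was not tested, except that fits on fewer samples have less power.

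The replicate number as a block gave 14 lists and 0 genes in limma, and called the metabotropic glutamate receptor list (adjusted p = 0.0324, and 0.532 with an estimated correlation). Same-numbered samples correlated in their deviations at 0.23, 0.25, 0.069 and 0.11, and every context control correlated best with a conditioned sample of another number, so the numbers are no evidence of a paired design.

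Mean log2 changes that turned sign were, with median-of-ratios scaling, respiratory chain (-0.0012); with quantile normalization, Homer1 (-0.024), GABA receptors (-0.010), respiratory chain (-0.019) and postsynaptic density (-0.019); with array weights, Egr1 (0.10), Nr4a1 (0.16), Arc (0.056) and Homer1 (-0.058); with GC correction, with and without the block, interneuron (-0.0056) and respiratory chain (-0.017); with edgeR, Nr4a1 (0.066) and Sostdc1 (0.019); with DESeq2, Nr4a1 (0.069).

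In replicates 1 and 2 only they were Egr1 (0.27), Nr4a1 (0.68), Arc (0.49), Homer1 (-0.0083), Dusp1 (0.054), Trib1 (0.083), Mll1 (-0.038), Slc13a4 (0.29), endoplasmic reticulum stress (0.023), deep layer (-0.12), upper layer (0.17), GABA receptors (-0.027), glucocorticoid (0.051), heat shock (0.076), meninges (0.35), microglia (0.026) and ribosomal (0.088). In replicates 3 and 4 only they were Fos (-0.13), Fosb (-0.25), Junb (-0.50), Egr2 (-0.56), Bdnf (-0.10), Fcrls (-0.014), effectors (-0.28), immediate early (-0.41), interneuron (-0.059), respiratory chain (-0.17), postsynaptic density (-0.031) and striatum (0.17).

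With single samples left out, sign turned within these ranges: effectors -0.083 to 0.14, immediate early -0.16 to 0.19, Arc -0.50 to 0.12, Egr1 -0.16 to 0.10, Egr2 -0.17 to 0.40, Homer1 -0.080 to 0.13, Nr4a1 -0.43 to 0.23, upper layer -0.23 to 0.17, GABA receptors -0.060 to 0.11, glucocorticoid -0.18 to 0.016, heat shock -0.13 to 0.031, histone acetylation -0.023 to 0.095, interneuron -0.042 to 0.11, respiratory chain -0.070 to 0.15, postsynaptic density -0.045 to 0.13 and ribosomal -0.35 to 0.033.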

Other observations

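The fit on replicates 1 and 2 only and the GC correction were chosen after the result was seen. Transcripts of secreted odorant-binding, androgen-binding and urinary proteins, best known from glands and liver, appeared in fear conditioning replicates 1 and 2, and these genes were chosen after their values were seen. The odorant-binding protein gene Obp1a read 127 and 195 there and was listed at 0 in the other 6 samples. The androgen-binding protein genes followed, with Abpe at 96.7 and 139 and Apbh at 81.5 and 150, against at most 1.34 elsewhere. Mup4, a major urinary protein gene, read 29.0 and 49.1 against at most 3.22. Obp1a and the unnamed locus Gm5938 were the 2 genes past the threshold in a limma fit on replicates 1 and 2 only (adjusted p = 0.0278 and 0.0359). These families hold near-identical copies, so the assignment of reads to a single member is uncertain.

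The myelin transcripts Ermn and Mog, also chosen after their values were seen, were highest in context control replicate 3. Ermn read 881 there against 42.4 to 206 in the other 7 samples, and Mog 514 against 46.4 to 159. The complement gene C3 read 141 there against at most 6.905, whereas Myoc, a gene also expressed in meninges, was highest in fear conditioning replicate 2 (313 against 257 in context control replicate 3).

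The immediate early and effector lists were higher with conditioning in replicates 1 and 2 and lower in replicates 3 and 4. Members of these lists are GC rich (median 53.1% against 49.7% of all tested genes), and GC content bias between libraries is a candidate explanation. After GC correction the difference between the changes was 0.62 with a standard error of 0.27, against 0.75 before (standard error 0.23). Both values come from the same 8 samples, so these errors reflect spread among samples rather than what the correction removed. After correction the changes kept their directions, at 0.32 in replicates 1 and 2 and -0.31 in replicates 3 and 4. Random lists matched on expression and GC content had a median difference of 0.13. For the 59 members as a set, these values argue against GC bias as the source of most of the difference. The mean lay at percentile 100 of 10000 random lists matched on expression and GC content, but such lists ignore the correlation among these genes, and with it estimated the adjusted p was 0.362 for each list. The exact permutation p of 0.0556 for both together is the smallest its design allows and does not decide, so chance stays open, and a difference between animals or batches stays open and untested.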
